A study of Mus musculus with 12 samples.

How the data were processed

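Male mice on a C57BL/6J background, backcrossed for at least 10 generations, were sampled at 5 to 6 months of age, and muscle and testis were collected between ZT6 and ZT7, per the labels' protocols. RNA was extracted from about 20 mg of powdered tissue, samples with an RQN above 7.2 were used, and polyA-selected libraries were sequenced as paired reads of 150 bases, per the labels' protocols. There were 12 libraries in 4 groups of 3, by tissue and genotype. The submitters' processing notes name fastp 0.23.4, HISAT2 2.1.0, Picard 1.119, HTSeq 0.11.2, DESeq2 1.46.0 and the build GRCm38.p4, without saying what each did, and they state neither a test nor how strand was treated.

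The authors deposited 2 tables. The first holds signal values per gene, which the authors made as read counts divided by 1 size factor per library over all 12 libraries, for 47730 features, of which 12084 have no reads in any library. Multiplied by a step found for each library, 100% of its values were whole numbers to within 0.001, and these recovered reads, 12852427 to 15795722 per library, give the depth. The second deposited table holds regularised log2 (rlog) values of 27384 of the features, which per the file headers cover the same libraries. Both tables include a feature named NeoR, and 419 features have no symbol. Values of testis library D labelled mutant had been turned into dates for 26 genes in both files, so they were treated as missing, and these genes were left out of the testis tests and the tests of the difference between tissues. Columns carry mouse numbers and tissue, and 7 mouse numbers occur, 5 of them in both tissues. The replicate numbers in the sample titles are not tied to these numbers, so letters stand for the mouse numbers. Positions were taken from GENCODE release M21 on GRCm38 for 47310 features.

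The comparisons, tests, filters, gene lists, naming rule and alternatives were set, except where said otherwise, before the data were examined. Within each tissue, log2(normalised count + 1) was compared between the genotype groups with limma 3.58.1 (lmFit and eBayes with a trend, two-sided) in R 4.3.3, on genes with a normalised count of at least 10 in at least 3 of the tissue's 6 libraries. P values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p below 0.05. With 3 libraries against 3, a permutation test of a single gene cannot go below p = 0.1, so the variances were estimated across genes. The difference between the tissues was the interaction of genotype and tissue in a limma model of all 12 libraries, on genes past the filter in both tissues. For testis, the groups are those of the labels, although Bckdk was not lower in the libraries labelled mutant.

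Of 42 gene lists of pathways, cell types and stress responses, those with at least 4 measured members were tested with camera at a preset correlation of 0.01, 30 in muscle and 32 in testis, with adjustment over the lists of the tissue. Camera with an estimated correlation and fry are given beside it. A result adjusted over the list alone is a Benjamini-Hochberg adjustment over that list's members. Medians of lists are medians of log2 changes. They and the counts of higher and lower members are relative to 0, whereas camera compares a list with the other genes tested. The median log2 change of all genes tested was -0.040 in muscle, 0.034 in testis and -0.080 for the difference between tissues. The naming rule took Bckdk, then per tissue up to 10 called genes with the largest rise and 10 with the largest fall that had a mean of at least 50 and groups that did not overlap. It also took up to 4 called members per list or else the 2 members with the smallest p, the 10 genes with the smallest p where fewer than 5 were called, and the 5 genes with the smallest p in each direction for the difference between tissues. Predicted genes and pseudogenes were counted but not named by the rule, and any that are named were chosen after their values were seen. Calls in both tissues were compared with the number expected from independent lists, and calls within 10 Mb of Bckdk with those elsewhere, by two-sided Fisher's exact tests. Tests of small p values along chromosome 7, and a count with overlapping genes taken as 1 locus, were added after the data had been examined.

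Transcripts of other tissues were measured after the data had been examined, with the sets described beside the values and with 12 genes of islet cells and 10 of pancreatic enzyme-secreting cells. A library was counted as having more islet transcripts when its islet sum was over 1.25 times the median of its tissue. Processed pseudogenes were matched to other genes with BLAST 2.17.0+. The alternatives were pseudocounts of 0.5 and 8, no filter or a mean of at least 50, scaling within the tissue by the median of ratios or by TMM, and the deposited rlog values. Others were edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads, eBayes without a trend, all 12 libraries in one model, the mouse as a block for the difference between tissues, windows of 5 and 20 Mb, and leaving out each library in turn. After the data had been examined, 3 more were added, namely the islet difference as a term in the model, the libraries with more islet transcripts left out, and genes below 3% of their level in the other tissue left out.

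The tests were checked on simulated counts with known changes. In muscle (15944 genes) limma recovered 10% of genes changed 1.5-fold, 64% changed 2-fold and 100% changed 4-fold or 8-fold. In testis (19210 genes) it recovered 64%, 98%, 100% and 100%, and for the difference between tissues (14351 genes) 4.44%, 45.3%, 95.3% and 100%. It also called 15 other genes in muscle (9.87% of its calls), 13 in testis (6.70%) and 16 for the difference (7.02%). A muscle list shifted by 0.5 on the log2 scale was recovered by camera with the preset correlation and was not with an estimated correlation, and 0 of 29 other lists were called. The simulated genes were drawn independently of each other, so this does not check camera on lists whose members move together. In real muscle the estimated correlation was 0.506 for slow-fibre genes and 0.795 for adipocyte markers. Splits of the muscle libraries other than the real one called 4 to 12 lists. Figures and tables were made with Python 3.11.15.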

Results

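RNA was sequenced from skeletal muscle (gastrocnemius and plantaris together) and from testis of male mice aged 5 to 6 months that were either wild type (Bckdk+/+) or carried the mutant allele on both chromosomes (BckdkM/M, called KO in the sample titles). Bckdk encodes the kinase that switches off the branched-chain ketoacid dehydrogenase, the committed step of branched-chain amino acid (BCAA) breakdown. The 12 libraries formed 4 groups of 3. A letter stands for the mouse number in each column, so that the muscle groups were wild-type A, B and C and mutant D, F and G, and the testis groups were wild-type A, B and C and D, E and F labelled mutant. The files held 14566523, 15783292 and 14782722 counted reads for wild-type muscle A, B and C. Mutant muscle D, F and G had 15404386, 15558080 and 14914486. Wild-type testis A, B and C had 14213960, 14979408 and 15080981, and testis D, E and F labelled mutant had 12852427, 15795722 and 14673843. Mitochondrially encoded genes took 7.65% to 8.21% of the reads in 5 muscle libraries, 11.5% in mutant muscle library G, and 0.76% to 0.84% in testis. Group values below are means of normalised counts ± SD with n = 3 libraries per group.

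Bckdk (ENSMUSG00000030802, chromosome 7, 127904082 to 127910221 in GRCm38) was almost absent from mutant muscle. Its normalised count was 2214, 2421 and 2627 in wild-type muscle A, B and C and 14.8, 14.3 and 12.4 in mutant muscle D, F and G. The group means of 2420 ± 206 and 13.8 ± 1.2 gave a log2 change of -7.35 (SE 0.16, adjusted p = 1.66e-09), and the mutant mean was 0.572% of the wild-type mean. In testis Bckdk was expressed at 2.92% of its level in wild-type muscle, with values of 68.0, 73.3 and 71.0 in wild-type A, B and C. The testis libraries labelled mutant had higher values, 138, 119 and 114 in D, E and F (log2 change 0.79, SE 0.15, adjusted p = 0.349), a difference that did not pass the test over all genes and that goes against the label. The deposited tables also hold a feature named NeoR, a neomycin resistance gene with no position in the mouse genome. NeoR averaged 3.13 ± 0.79 in wild-type and 242 ± 30.3 in mutant muscle (log2 change 5.89, SE 0.31, adjusted p = 8.82e-06, 59.3-fold). In testis it averaged 2.54 ± 0.79 in wild type and 17.2 ± 3.61 in the libraries labelled mutant (log2 change 2.37, SE 0.47, adjusted p = 0.374), and passed there with all 12 libraries in one model. By the column numbers, mice D and F gave both tissues, and their muscle is among the low values. Because the target gene and NeoR point in different ways in testis, testis directions below are given by label, as libraries labelled mutant against wild type.

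**Figure D1:**
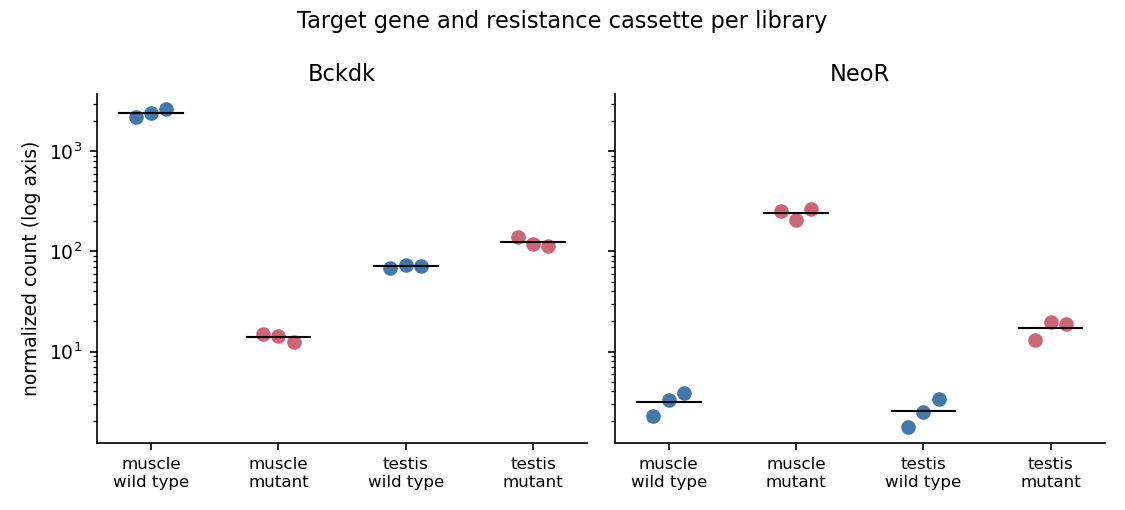
Normalised counts on a log axis of Bckdk (left) and NeoR (right) in each of the 12 libraries, by tissue and labelled genotype; points are libraries and lines are group means. Mutant muscle lies at 12.4 to 14.8 for Bckdk against 2214 to 2627 in wild-type muscle, whereas testis libraries labelled mutant lie at 114 to 138, above wild-type testis.

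Each tissue's libraries also held transcripts of other tissues, at levels that differed between libraries. The 100 most abundant testis genes whose mean muscle level was below 3% of their testis level were followed in each muscle library. Their median was 1.08%, 1.01% and 1.20% of the testis level in wild-type A, B and C and 1.27% in mutant D. It was 0.450% and 0.446% in mutant F and G. Muscle genes taken the same way stood in testis at 0.767% to 0.856% in wild-type C and in D, E and F labelled mutant, at 0.510% in wild-type A and at 0.291% in wild-type B. In B these genes did not follow their muscle levels (Spearman's rho 5.40e-05 across genes, 0.674 to 0.798 in the other testis libraries). The fast myosin gene Myh4 was at 5.00 there, against 1464 in A and 3523 to 3891 in the others. Genes of pancreatic islet cells, led by the insulin gene Ins2, summed to 13782 to 16235 normalised counts in muscle A, B, C and D and to 33388 and 31339 in muscle F and G. The same sum was 19745 and 19565 in wild-type testis A and B and 10710 to 13925 in the other testis libraries. The libraries with more islet transcripts were thus 2 of the 3 mutants in muscle and 2 of the 3 wild types in testis. Leaving them out sets mutant D alone against 3 wild types in muscle and wild-type C alone against 3 libraries in testis, with the lone library assumed to vary like the others.

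**Figure D2:**
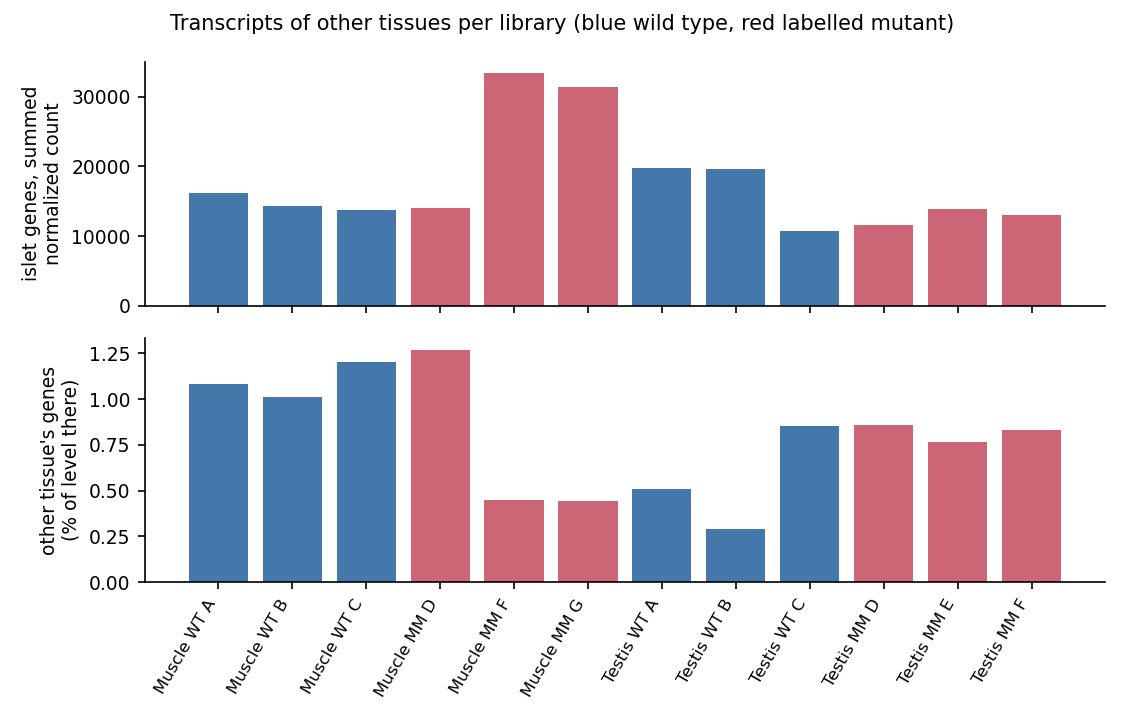
Summed normalised counts of 12 islet genes (top) and the median level of the other tissue's genes in percent of their level there (bottom), for each of the 12 libraries (blue wild type, red labelled mutant). Muscle F and G and testis A and B have the highest islet sums, 33388, 31339, 19745 and 19565, and the lowest levels of the other tissue's genes.

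The muscle comparison asked which genes differ in mutant muscle, a tissue tied to the motor coordination named in the series title. Besides Bckdk and NeoR, the called gene taken by the naming rule was Gdpd3 (ENSMUSG00000030703, chromosome 7, 126766334 to 126775649), which encodes a lysophospholipase D. It rose 23.9-fold, from 20.1 ± 8.03 in wild-type to 485 ± 132 in mutant muscle (log2 change 4.58, SE 0.32, adjusted p = 8.47e-05), with all 3 mutant values above all 3 wild-type values. The other calls were 3 features outside the naming rule, chosen after their values were seen. Gm9967, which overlaps Gdpd3 on the other strand, so that reads of the pair are not separable without strand, went from 20.96 ± 9.73 to 177 ± 40.6 (log2 change 3.12, adjusted p = 0.0151). The processed pseudogenes Rps13-ps1 and Mrpl48-ps, whose reads can be shared with their near-identical parent genes, went from 33.2 ± 5.89 to 524 ± 126 (adjusted p = 1.12e-05) and, for Mrpl48-ps, from 0.361 ± 0.625 to 34.8 ± 9.61 (log2 change 4.77, adjusted p = 0.0428). In all, 6 of 16246 genes passed, 5 higher and 1 lower in mutant muscle. At an unadjusted p below 0.05 there were 1546 genes (9.52%), and for 2267 genes the 2 groups did not overlap (13.95%, where chance gives 10%). The count was 36 with DESeq2 (23 higher and 13 lower), 28 with all 12 libraries in one model (8 higher and 20 lower), and 14 with no filter on low values (8 higher and 6 lower). It was 10 without wild-type library B, with the slow-fibre genes Tnni1, Myh7 and Tnnt1 among those gained, and 3 without mutant library F. Without mutant library D it was 497 (89 higher and 408 lower). The only mutants were then the high-islet libraries F and G, so genotype and islet difference cannot be told apart there. The 497 included 145 genes at under 3% of their testis level, all lower, and 10 of the 12 islet genes, all higher. Slc7a2, mt-Nd3, Casq2, Ankrd1, Chrnb1 and Camk2a were also among them. In each fit without a mutant library, NeoR and Mrpl48-ps fell below the filter, which they passed only through the 3 mutants. They were not tested there, so their absence from those counts is not a lost call. The call of Gm9967 in muscle was lost without wild-type C (adjusted p = 0.0636), mutant F (0.0933) or mutant G (0.0648), within a range over the alternatives of 1.14e-15 to 0.343. That of Mrpl48-ps in muscle was lost without wild-type A (0.0678) or wild-type C (0.153), within a range of 6.34e-04 to 0.242.

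Slow-fibre genes, which encode the contractile proteins of slow-twitch muscle, rose as a group in mutant muscle. Of 15 measured members 13 had higher means and 2 lower (median log2 change 1.03, adjusted p = 1.49e-08 by camera, and 0.54 with an estimated correlation). Over all genes 0 members passed, and 10 passed, all higher, when adjusted over the list alone. Without wild-type B, the highest wild type, Tnni1, Myh7 and Tnnt1 passed over all genes (log2 changes 3.15, 4.59 and 2.97). Casq2, the slow-fibre calsequestrin, went from 298 ± 42.2 to 503 ± 63.8, and slow troponin I (Tnni1) from 91.3 ± 112 to 249 ± 61.6. Slow myosin heavy chain (Myh7) was 22.8, 1662 and 80.9 in wild-type A, B and C and 1160, 1066 and 975 in mutant D, F and G. The list median per library, relative to the wild-type mean, was -0.72, 0.76 and -0.18 in the wild types and 0.68, 1.21 and 1.47 in D, F and G, with the high-islet libraries highest. Genes of excitation and calcium release fell as a group (3 higher and 21 lower of 24, median -0.28, adjusted p = 5.83e-04, and 0.604 with an estimated correlation), with Camk2a at 9691 ± 269 and 6456 ± 2396. No member passed over all genes or when adjusted over the list alone. Without mutant G the median was -0.17, and without the high-islet libraries it was 0.00. In D, F and G it stood at 0.00, -0.32 and -0.61. The atrophy list fell (2 higher and 17 lower of 19, median -0.24, adjusted p = 0.00779, and 0.54 with an estimated correlation), and without mutant F (median -0.15) it no longer passed, as also without both high-islet libraries (-0.14). Adjusted over the list alone, 1 member was higher, Tnfrsf12a, a receptor of the TNF family (225 ± 56.1 to 411 ± 109), and 1 was lower, the transcription factor Klf15 (739 ± 46.4 to 517 ± 62.9). Fast-fibre genes (2 higher and 15 lower of 17, median -0.16, adjusted p = 0.138), growth signalling (7 and 16 of 23, -0.11, 0.161) and muscle stem cell and regeneration genes (8 and 7 of 15, 0.05, 0.12) did not pass. Of these, only the stem cell list had a member past the threshold when adjusted over the list alone, Myl4 (66.7 ± 8.03 and 129 ± 26.6). Genes of the nerve-muscle junction and denervation did not pass either (9 and 14 of 23, median -0.08 but mean 0.13 and camera direction up, adjusted p = 0.161). Adjusted over that list alone, 2 of its members were higher, the acetylcholine receptor subunit Chrnb1 (410 ± 36.1 and 635 ± 19.5) and Ankrd1 (112 ± 30.3 and 245 ± 46.6).

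Genes of oxidative phosphorylation rose slightly in mutant muscle and those of glycolysis fell by camera (adjusted p = 0.667 for both with an estimated correlation), while BCAA breakdown genes did not pass. For oxidative phosphorylation 25 of 37 members were higher and 12 lower (median 0.12, adjusted p = 0.0051), and for glycolysis 5 of 25 were higher and 20 lower (median -0.28, adjusted p = 0.0274). In both, 0 members passed over all genes or when adjusted over the list alone. Cox7b, a subunit of cytochrome oxidase, was 3934 ± 919 and 5267 ± 1125, and Pfkfb3, which makes the activator of phosphofructokinase, was 16308 ± 4025 and 8964 ± 1829. Oxidative phosphorylation no longer passed without wild-type A (median 0.03) and had a median of 0.24 without wild-type C. Glycolysis had -0.45 without mutant D and did not pass without wild-type B (-0.29) or C (-0.20) or mutant F (-0.23) or G (-0.11), while without both high-islet libraries the glycolysis median was 0.10. The 28 measured BCAA breakdown genes, the pathway that Bckdk restrains, were 14 higher and 14 lower (median -0.00, adjusted p = 0.987, and passing as lower without mutant G with a median of -0.08), with Pcca at 1132 ± 82.4 and 936 ± 119. Fatty acid oxidation (18 higher and 10 lower of 28, median 0.07, adjusted p = 0.161) and mitochondrial stress genes (3 and 9 of 12, -0.11, 0.164) did not pass. Mitochondrial transcripts (9 and 4 of 13, 0.13, 0.163) did not pass as a list, in which mt-Nd3 alone was past the threshold when adjusted over the list alone (350 ± 63.0 and 766 ± 281).

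Immediate early genes, which respond within minutes to stimuli, fell together in mutant muscle. All 20 measured members were lower (median -0.43, adjusted p = 4.22e-05, and 0.54 with an estimated correlation). Over all genes 0 passed, and 6 did when adjusted over the list alone, among them Fos (544 ± 253 and 167 ± 90.6), Jun (2145 ± 148 and 1474 ± 155) and Nr4a1 (3614 ± 781 and 1971 ± 714). Without mutant D the median was -0.28. The cytosolic tRNA synthetases, which charge tRNAs with amino acids, were lower in 20 of 20 members by small amounts (median -0.19, adjusted p = 0.00287, and 0.604 with an estimated correlation). None of them passed over all genes or when adjusted over the list alone, and without the high-islet libraries the median was -0.03. Clock genes fell (6 higher and 13 lower of 19, median -0.31, adjusted p = 0.0171, and 0.604 with an estimated correlation). Per2 (288 ± 45.4 and 126 ± 80.6) and Hlf (397 ± 18.7 and 235 ± 66.1) were lower when adjusted over the list alone, and 0 members passed over all genes. The clock list no longer passed without wild-type C (median -0.24), without both high-islet libraries (-0.07) or without a trend in the variances. Its median was -0.07, -0.21 and -0.73 in mutant D, F and G, and -0.08 without G and -0.47 without D. The amino acid stress response did not pass (17 higher and 15 lower of 32, median 0.04, adjusted p = 0.262), but 3 of its members did when adjusted over the list alone. The glutathione-degrading enzyme Chac1 was lower (1925 ± 1092 and 470 ± 115) and passed over all genes without wild-type A, and the transcription factor Atf5 (1208 ± 155 and 1778 ± 68.8) and the pseudokinase Trib3 (17.3 ± 6.74 and 48.2 ± 11.1) were higher. Amino acid transporters (6 and 11 of 17, median -0.15, adjusted p = 0.212) had 1 member past the threshold when adjusted over the list alone, the cationic transporter Slc7a2 (1526 ± 329 and 795 ± 103). Heat shock genes (3 and 11 of 14, -0.10, 0.161) had 3 such members, all lower, among them Dnajb1 (463 ± 104 and 268 ± 57.5), and glucocorticoid response genes (7 and 12 of 19, -0.23, 0.702) had 2, Dusp1 and Klf15, both lower. Autophagy and lysosome (13 and 15 of 28, -0.01, 0.702) and polyamine metabolism (4 and 8 of 12, -0.04, 0.702) did not pass and had 0 such members.

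Markers of red blood cells, tendon, fat cells, macrophages and endothelium, and collagen and interferon genes, rose in mutant muscle by camera. With an estimated correlation these 7 lists did not pass (lowest adjusted p = 0.54). Red blood cell markers were higher in 7 of 7 members (median 0.68, adjusted p = 8.46e-07, and 0.54 with an estimated correlation). Over all genes 0 passed, and 4 did when adjusted over the list alone, among them Alas2 (89.0 ± 7.77 and 143 ± 6.70) and Hbb-bs (1297 ± 18.98 and 2363 ± 700). The globin genes share sequence with their copies, so that reads can be split between them. Hbb-bs also lies on chromosome 7 within 35 Mb of Bckdk, and is among the genes with a small p counted there below. Tendon markers were higher in 10 of 10 (median 0.55, adjusted p = 3.51e-04, and 0.54 with an estimated correlation), with the matrix proteoglycan Kera alone past the threshold when adjusted over the list alone (30.5 ± 17.6 and 76.9 ± 25.2). The tendon list no longer passed without mutant F (median 0.35), and without both high-islet libraries it passed with a median of 0.17. Its median was -0.17, -0.34 and 0.52 in wild-type A, B and C and 0.27, 0.94 and 0.31 in mutant D, F and G, so that wild-type C lay above D and G. For 5 more lists that rose, 0 members passed over all genes or when adjusted over the list alone. Collagen and matrix genes (17 higher and 3 lower of 20, median 0.20, adjusted p = 4.44e-04, and 0.54 with an estimated correlation) included Col1a2 at 3543 ± 156 and 4579 ± 293. They had medians of 0.10 without wild-type C and 0.12 without mutant F, and without the high-islet libraries they no longer passed (0.07). Adipocyte markers (14 of 14 higher, median 0.67, adjusted p = 4.44e-04, and 0.604 with an estimated correlation) also rose. They were highest in mutant G and lowest in wild-type C, with Cfd at 9808, 9209 and 2266 in A, B and C and 10801, 8416 and 36079 in D, F and G. Without wild-type C their median was -0.16, without wild-type A 1.37 and without mutant G 0.33. Macrophage (13 and 3 of 16, median 0.16, adjusted p = 0.0265, and 0.667 with an estimated correlation), interferon (17 and 5 of 22, 0.16, 0.027, and 0.667) and endothelial genes (11 and 4 of 15, 0.14, 0.0274, and 0.54) also rose. Each of these no longer passed without wild-type C (medians 0.11, 0.06 and 0.08) or without mutant G (0.09, -0.06 and 0.10), and macrophage markers also without mutant F (0.06). Without mutant D the medians of macrophage and interferon genes were 0.34 and 0.33, and without mutant F that of interferon genes was 0.27. Interferon and endothelial genes did not pass with all 12 libraries in one model either, nor endothelial genes without a trend in the variances. With D as the lone mutant, when both high-islet libraries were left out, macrophage markers in muscle passed as lower (median -0.16, adjusted p = 0.0312, within a range over the alternatives of 5.13e-04 to 0.316), and interferon (-0.11), endothelial (0.07) and adipocyte genes (0.26) did not pass. Schwann cell markers (10 and 3 of 13, median 0.16, adjusted p = 0.149) did not pass, with 0 members past the threshold over all genes or when adjusted over the list alone. In all, 15 of 30 lists passed in muscle, 9 higher and 6 lower, against 0 with an estimated correlation (lowest adjusted p = 0.54) and 0 by fry (lowest adjusted p = 0.154), and no member of any list passed over all genes. The number was 9 without wild-type library C and 8 without the high-islet libraries. Of the lists that did not pass, some did with 1 library left out. They were mitochondrial transcripts (median 0.18) and fatty acid oxidation (0.12) without D, and heat shock without A (-0.19) or G (-0.14). Others were the nerve-muscle junction without G (-0.00), BCAA breakdown without G, as lower, and Schwann cell markers without F (0.31). Heat shock (-0.11) and glucocorticoid response genes (-0.16) also passed with D as the lone mutant, and stem cell genes with no filter (0.06).

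**Figure D3:**
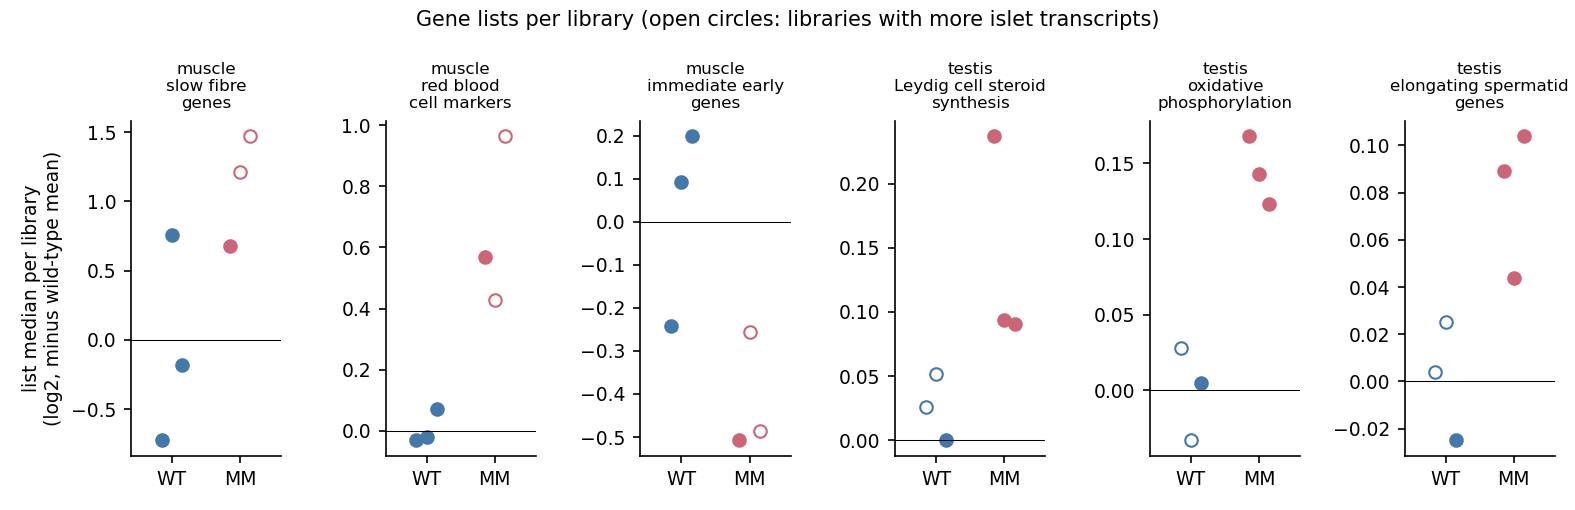
Median log2 value of 3 muscle lists (slow fibre, red blood cell, immediate early) and 3 testis lists (Leydig, oxidative phosphorylation, elongating spermatid) in each library, relative to the wild-type mean; open circles mark libraries with more islet transcripts. For slow-fibre genes the wild-type muscle libraries spread from -0.72 to 0.76 and the mutants from 0.68 to 1.47.

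The testis comparison bears on the luteinising hormone response and testosterone synthesis that the series title names. The Leydig cell list, genes of testosterone-producing cells, rose in libraries labelled mutant, in which Bckdk itself was not lower (adjusted p = 8.19e-04 by camera, and 0.29 with an estimated correlation). Klk1b21 (ENSMUSG00000066516, chromosome 7, 44102328 to 44106583), a kallikrein gene of that list, went from 36.9 ± 5.23 to 103 ± 19.3 (log2 change 1.455, SE 0.20, adjusted p = 0.0489); it belongs to a family of near-identical paralogs whose reads can be shared. Myo7a (ENSMUSG00000030761, chromosome 7, 98051060 to 98119524), an unconventional myosin, fell from 2009 ± 8.25 to 1537 ± 18.3 (log2 change -0.39, SE 0.053, adjusted p = 0.0489). The pseudogenes Rps13-ps1 (27.1 ± 2.25 to 337 ± 101, adjusted p = 2.23e-05) and Gm10167 (0.278 ± 0.481 to 22.4 ± 2.99, adjusted p = 0.0489), chosen after their values were seen, completed the calls. Thus 4 of 19543 genes passed, 3 higher and 1 lower, while 1386 genes (7.09%) had an unadjusted p below 0.05 and 2618 (13.4%, where chance gives 10%) had groups that did not overlap. The next smallest p values, none of which passed, belonged to Tmc7 (2616 ± 217 and 1720 ± 317, adjusted p = 0.309), Tmc5 (1139 ± 30.3 and 1452 ± 60.8, 0.309) and the ribonucleotide reductase subunit Rrm1 (1226 ± 47.4 and 1549 ± 41.6, 0.309). After them came Bckdk, the transporter Spns1 (163 ± 26.1 and 88.2 ± 12.6, 0.349) and Dynlt1-ps1 (1484 ± 88.3 and 1914 ± 128, 0.349). The count was 1 without wild-type A, wild-type B or mutant-labelled D, or without both high-islet libraries. It was 10 with DESeq2 (5 higher and 5 lower), 2 on the rlog values, 0 without a trend in the variances, and 1 with a pseudocount of 0.5, with TMM scaling or with a mean filter of 50. Klk1b21 did not pass when any 1 of the 6 libraries was left out (adjusted p = 0.0667 to 0.581, and 3.90e-05 to 0.788 over the alternatives). Of these fits Myo7a passed only in that without E labelled mutant (adjusted p = 0.0304 to 0.581, and 1.24e-05 to 1 over the alternatives). Gm10167 in testis no longer passed without wild-type A (0.22) or B (0.055), within a range over the alternatives of 0.00553 to 0.425. Without any 1 library labelled mutant it fell below the filter and was not tested.

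In the Leydig cell list 19 of 25 members were higher and 6 lower in libraries labelled mutant (median 0.11, adjusted p = 8.19e-04, and 0.29 with an estimated correlation), with a median of 0.19 without E labelled mutant. Over all genes 1 member passed, Klk1b21, and 4 passed when adjusted over the list alone. Cyp17a1, which makes androgen precursors, was at 1633 ± 156 and 2223 ± 404, and the kallikrein genes Klk1b27 at 20.99 ± 8.49 and 61.8 ± 21.7 and Klk1b24 at 36.9 ± 7.95 and 63.9 ± 5.58. LH and cAMP signalling genes did not pass (15 higher and 8 lower of 23, median 0.03, adjusted p = 0.99; mean 0.03 but camera direction down), with the LH receptor Lhcgr at 52.2 ± 11.5 and 72.2 ± 10.3. Cholesterol synthesis (21 and 4 of 25, median 0.12, adjusted p = 0.0614), Sertoli cell markers (15 and 11 of 26, 0.03, 0.968) and androgen-regulated Sertoli genes (4 and 8 of 12, -0.03, 0.0943) did not pass. These 4 lists had 0 members past the threshold over all genes or when adjusted over the list alone. Their members with the smallest p included the cholesterol enzymes Mvk (82.0 ± 9.78 and 118 ± 14.7) and Dhcr7 (133 ± 16.8 and 175 ± 3.45). Others were the inhibin subunit Inha (514 ± 23.7 and 621 ± 66.8) and the potassium channel Kcnk3 (34.2 ± 3.57 and 18.5 ± 3.41). Dhcr7 lies 15.93 Mb from Bckdk on chromosome 7, and is among the genes with a small p counted there below.

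Elongating spermatid, meiosis and round spermatid genes rose by small amounts in libraries labelled mutant, and spermatogonia markers did not pass. Elongating spermatid genes were higher in 22 of 24 (median 0.10, adjusted p = 7.54e-05, and 0.246 with an estimated correlation). Spem1 was past the threshold when adjusted over the list alone (4309 ± 38.8 and 4908 ± 51.5), 0 members passed over all genes, and the transition protein gene Tnp1 was at 14206 ± 1562 and 17352 ± 3230. With all 12 libraries in one model none of the 3 lists passed. Meiosis genes (21 higher and 6 lower of 27, median 0.08, adjusted p = 0.0263, and 0.29 with an estimated correlation) and round spermatid genes (21 and 2 of 23, 0.07, 0.0301, and 0.471 with an estimated correlation) rose too. They had 0 members past the threshold over all genes or when adjusted over the list alone. Without wild-type A (median 0.06), wild-type B (0.06), or D (0.05) or F (0.08) labelled mutant, meiosis genes no longer passed. Round spermatid genes did not without wild-type A (0.05) or D (0.05) or F (0.03) labelled mutant. Neither list passed with scaling within the tissue by the median of ratios (medians 0.05 and 0.03) or by TMM (0.05 and 0.03), with a mean filter of 50, without a trend in the variances or when both high-islet libraries were left out (0.04 and 0.04). Spermatogonia markers did not pass (9 and 9 of 18, median 0.01 but mean -0.03 and camera direction down, adjusted p = 0.485, with 0 members when adjusted over the list alone).

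All 37 oxidative phosphorylation genes were higher in libraries labelled mutant (median 0.15, adjusted p = 1.16e-11). The adjusted p was 0.246 with an estimated correlation and 0.0427 by fry, which asks whether the genes move one way on balance. No member passed over all genes or when adjusted over the list alone, with Sdhb at 728 ± 28.5 and 842 ± 28.8 and Ndufa4 at 155 ± 33.2 and 211 ± 22.1. Mitochondrial transcripts rose too (10 higher and 1 lower of 11, median 0.10, adjusted p = 6.82e-04, and 0.337 with an estimated correlation). Over all genes 0 members passed, and 3 did when adjusted over the list alone, among them mt-Nd6 (2237 ± 97.4 and 2652 ± 171). Without the high-islet libraries (median 0.09) or with all 12 libraries in one model the list did not pass, and without wild-type A its median was 0.15. Glycolysis genes rose (20 and 6 of 26, median 0.11, adjusted p = 0.00601, and 0.471 with an estimated correlation) with 0 members past the threshold over all genes or when adjusted over the list alone. One of them, the muscle phosphorylase Pygm, was at 370, 83.3 and 825 in wild-type A, B and C and 852, 776 and 758 in D, E and F labelled mutant, a pattern that followed the muscle transcripts in these libraries. The glycolysis list no longer passed without wild-type B (median 0.07), without E labelled mutant (0.08), without both high-islet libraries (0.03), or without genes at under 3% of their muscle level (0.06). BCAA breakdown (20 and 8 of 28, median 0.10, adjusted p = 0.386) and mitochondrial stress genes (10 and 2 of 12, 0.05, 0.386) did not pass. Fatty acid oxidation did not either (18 and 10 of 28, median 0.07 and mean 0.01 but camera direction down, 0.776). These 3 lists had 0 members past the threshold over all genes or when adjusted over the list alone.

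Endothelial, interferon and collagen genes fell in libraries labelled mutant by camera and did not pass with an estimated correlation (lowest adjusted p = 0.29). Endothelial markers were lower in 13 of 15 (median -0.14, adjusted p = 1.73e-04, and 0.295 with an estimated correlation), with Kdr, a receptor for vascular endothelial growth factor, at 111 ± 26.4 and 73.6 ± 7.19. Their median was -0.08 without wild-type B, and -0.28 without wild-type C or without D labelled mutant. Wild-type C stood at -0.21, within the -0.12 to -0.32 of the libraries labelled mutant. Interferon genes (4 higher and 10 lower of 14, median -0.11, adjusted p = 0.0173, and 0.29 with an estimated correlation) and collagen and matrix genes (7 and 11 of 18, -0.10, 0.0174, and 0.29 with an estimated correlation) fell as well. These 3 lists had 0 members past the threshold over all genes or when adjusted over the list alone. Interferon genes had a median of -0.18 without wild-type A or without D labelled mutant, and of -0.35 without both high-islet libraries, where they still passed. They no longer passed without wild-type C (-0.04), with no filter (-0.11) or with a mean filter of 50 (-0.01), nor collagen without wild-type A (-0.07) or E labelled mutant (-0.06), and without both high-islet libraries neither endothelial markers (0.02) nor collagen (-0.15) passed. Macrophage (7 and 8 of 15, median -0.04, adjusted p = 0.376), and red blood cell markers (5 of 5 higher, 0.15, 0.102) did not pass. Neither did peritubular myoid (10 and 3 of 13, 0.08, 0.386), epididymis (5 and 1 of 6, 0.24, 0.153) and blood-testis barrier genes (9 and 10 of 19, -0.02, 0.154).

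Amino acid transporters were slightly lower in libraries labelled mutant, and the other amino acid and stress lists did not pass. The transporters were 5 higher and 9 lower of 14 (median -0.03, adjusted p = 0.034, and 0.29 with an estimated correlation), with Slc36a1 at 194 ± 15.9 and 153 ± 4.15. Their call was lost without wild-type A (median -0.06) or B (-0.01), without D (-0.03), E (-0.03) or F (-0.07) labelled mutant, without both high-islet libraries (-0.00), with no filter (0.00), without a trend in the variances and with all 12 libraries in one model. The amino acid stress response (18 higher and 13 lower of 31, median 0.02 and mean 0.01 but camera direction down, adjusted p = 0.776) included Gpt2 at 436 ± 47.6 and 535 ± 48.8. Cytosolic tRNA synthetases (17 and 3 of 20, median 0.04, adjusted p = 0.25), and autophagy and lysosome genes (22 and 6 of 28, 0.06, 0.296) did not pass. Polyamine metabolism (9 and 2 of 11, 0.04, 0.578) and heat shock genes (10 and 4 of 14, 0.05, 0.386) did not either. Clock genes (7 and 12 of 19, -0.02, 0.0624) and immediate early genes (6 and 12 of 18, -0.03, 0.0624) did not pass. Glucocorticoid response genes (12 and 7 of 19, adjusted p = 0.348) had a median of 0.02 but a mean of -0.03 and camera direction down. No member of the lists in this paragraph or the preceding one passed over all genes or when adjusted over the list alone. In all, 11 of 32 lists passed in testis, 7 higher and 4 lower, against 0 with an estimated correlation (lowest adjusted p = 0.246) and 1 by fry, and 5 by fry's test for change in either direction (lowest adjusted p = 0.00693, epididymis markers). Of the lists that did not pass, some did with 1 library left out, namely clock genes without wild-type B (median -0.03), immediate early genes without wild-type B (-0.07) or C (-0.05) or E (-0.12), and cholesterol synthesis without wild-type B (0.11) or F (0.14). Others were androgen-regulated Sertoli genes without wild-type C (-0.11) or E (-0.09) and the blood-testis barrier without wild-type C (-0.06). Clock genes also passed with a mean filter of 50 and cholesterol synthesis with no filter. The number was 7 without wild-type library A, 4 without the high-islet libraries and 6 with all 12 libraries in one model.

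The difference between the tissues asked whether the genotype effect in muscle differs from that by label in testis. Bckdk differed most, with a log2 change of -7.35 in muscle and 0.79 in testis (difference -8.14, adjusted p = 1.26e-10), and NeoR was raised more in muscle (difference 3.52, adjusted p = 0.0165). These were the 2 of 14677 genes that passed, 1 in each direction, with 1275 (8.69%) at an unadjusted p below 0.05. The call of NeoR was lost with edgeR, with DESeq2, with no filter and without wild-type testis B, whereas that of Bckdk was kept in these. The other genes with the smallest p did not pass. They were Gdpd3 (difference 4.02, adjusted p = 0.155), Casq2 (1.37, 0.295), Ankrd1 (2.02, 0.296) and Thbd (1.01, 0.393) above 0, and Aldoart1 (-1.52, 0.228), Fam167a (-1.41, 0.393), Dgkh (-1.03, 0.393) and Spaca9 (-1.18, 0.393) below 0. Testis transcripts stood at 0.450% and 0.446% of their testis level in muscle F and G, against 1.01% to 1.27% in the other muscle libraries. For such transcripts this alone gives differences below 0. How far it holds for these genes and for the counts that follow was not tested. The count was 50 with DESeq2 (2 above and 48 below 0), 951 without mutant muscle D (86 above and 865 below 0), 4 without wild-type muscle A (2 in each direction), and 1 without mutant muscle F or G, wild-type testis B or any testis library labelled mutant (D, E or F). It was also 1 with edgeR, with no filter or with a mean filter of 50. NeoR fell below the filter, and so was not tested, without any mutant muscle library or any testis library labelled mutant. The same held with a mean filter of 50.

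Of 20 lists measured in both tissues, 8 differed between them by camera and 0 with an estimated correlation (lowest adjusted p = 0.0546). Endothelial markers (median difference 0.36, adjusted p = 5.17e-05, and 0.243 with an estimated correlation), collagen and matrix (0.16, 4.43e-04, and 0.0546), interferon response (0.26, 0.00365, and 0.536) and glycolysis (-0.34, 0.00724, and 0.608) had passed in both tissues in opposite directions. Cytosolic tRNA synthetases (-0.24, 0.00154, and 0.536), macrophage markers (0.17, 0.00724, and 0.536), red blood cell markers (0.40, 0.0347, and 0.306) and immediate early genes (-0.22, 0.0347, and 0.608) had passed in muscle. The libraries with more islet transcripts were mutant in muscle (F and G) and wild type in testis. Relative to the wild-type mean, mutant muscle D, F and G had list medians of 0.10, -0.29 and -0.43 for glycolysis, -0.15, 0.32 and 0.35 for macrophage markers, and -0.03, -0.20 and -0.27 for tRNA synthetases. They were -0.51, -0.26 and -0.48 for immediate early genes and 0.57, 0.43 and 0.96 for red blood cell markers, where D did not stand apart from F and G. Oxidative phosphorylation passed in the same direction in both tissues (median difference -0.04, adjusted p = 0.891).

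Of the 14677 genes tested in both tissues, 4 were called higher in muscle and 1 in testis, and 1 was shared, Rps13-ps1 (2.7e-04 expected from independent lists, Fisher's exact p = 2.73e-04, two-sided). Among the genes called lower, 1 in each tissue, 0 were shared (Fisher's exact p = 1). Across these genes, which are not independent replicates, the log2 changes of the 2 tissues had Pearson's r of 0.026 and Spearman's rho of 0.042. An unadjusted p below 0.01 in both tissues was reached by 8 genes, 6 of them in the same direction, where 2.96 were expected from independence. They were Bckdk and Casq2, in opposite directions, and Tmc7, NeoR, Rps13-ps1, Mrpl48-ps, Dynlt1b and Tmem181b-ps. Tmc7 lies within 35 Mb of Bckdk, as do the best matches of Rps13-ps1 and Mrpl48-ps. By the column numbers 5 mice gave both tissues, so independence is not a full baseline. Dynlt1b and Tmem181b-ps lie on chromosome 17, away from the allele, and neither passed over all genes in either tissue. The span of 35 Mb was set after the values were seen. These 8 genes thus do not decide whether the tissues share a response apart from the allele and its surroundings. The shared number was 2 with DESeq2 or all 12 libraries in one model and 0 without a trend in the variances.

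Genes near the mutant allele were examined because DNA of the strain in which an allele is made can remain around it through backcrossing, here of at least 10 generations. In muscle, 2 of the 228 other genes tested within 10 Mb of Bckdk on chromosome 7, Gdpd3 and its overlapping partner Gm9967, passed, against 3 of 16017 elsewhere (odds ratio 47.2, Fisher's exact p = 0.00191, two-sided). Reads of that pair are not separable, and with overlapping genes counted once, a test added after the data had been examined, it was 1 of 136 loci against 3 of 12648 (Fisher's exact p = 0.0419). Within 20 Mb that test did not pass (1 of 261 loci, Fisher's exact p = 0.0792). Those 3 were NeoR, which has no position, and 2 pseudogenes. In testis, 0 of 266 passed by limma, against 4 of 19276 elsewhere (Fisher's exact p = 1), with 2 by DESeq2. Within 20 Mb, an unadjusted p below 0.01 was reached by 9 of 392 muscle genes (2.30%, Fisher's exact p = 0.213) and 17 of 450 testis genes (3.78%, Fisher's exact p = 4.58e-05), against 1.54% and 1.17% on other chromosomes. Within 5 Mb it was 3 of 152 in muscle (1.97%, Fisher's exact p = 0.51) and 5 of 167 in testis (2.99%, Fisher's exact p = 0.0491). Over a wider span, set after the values were seen, it was reached by 21 of 529 muscle genes (3.97%) within 35 Mb of Bckdk against 230 of 14956 (1.54%) on other chromosomes (Fisher's exact p = 1.49e-04). In testis it was reached by 25 of 592 (4.22%) against 210 of 17956 (1.17%, Fisher's exact p = 1.48e-07), and Myo7a, Tmc7, Tmc5, Rrm1 and Spns1 all lie in this span. Tmc7 was lower in both tissues, at -1.63 (SE 0.24, adjusted p = 0.0779) in muscle and -0.62 (SE 0.11, adjusted p = 0.309) in testis, and passed in neither. It was called in muscle with no filter, with DESeq2, with all 12 libraries in one model and without mutant G. The same held without mutant D, where the high-islet F and G were the only mutants. With D as the lone mutant its muscle change was -2.16. In testis it was called with DESeq2 and without F. The muscle count of 2 was 1 without wild-type C or mutant F or without a trend in the variances, and 6 without mutant D, and the testis count was 2 without F labelled mutant.

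**Figure D4:**
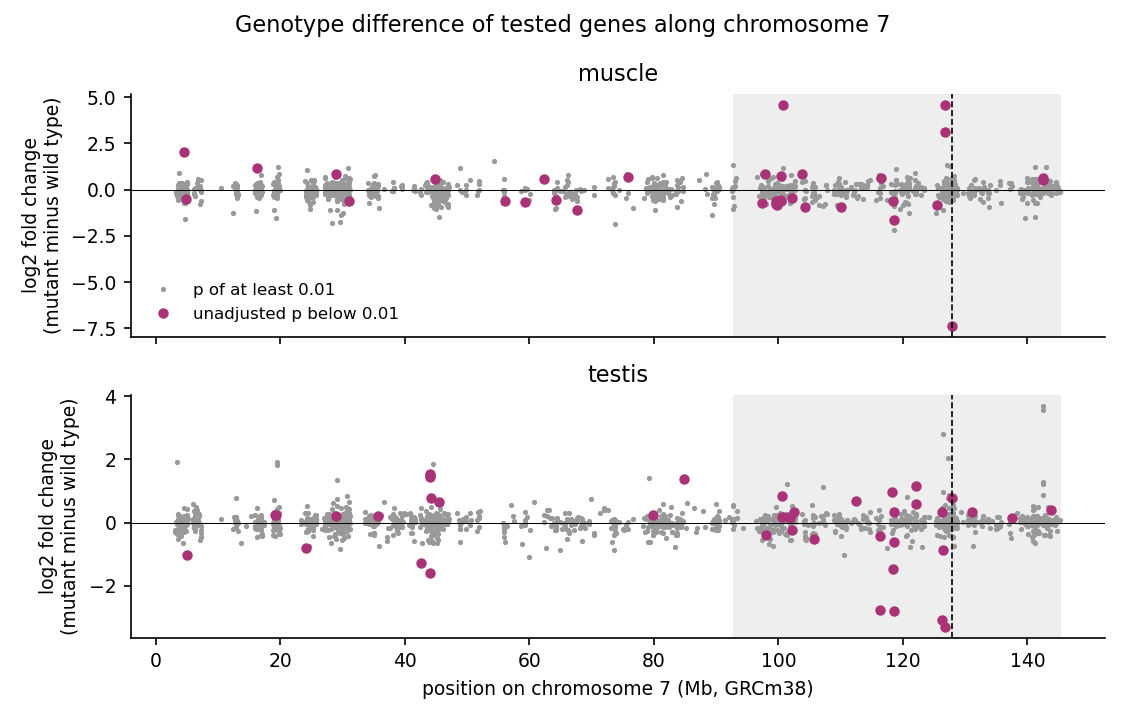
Log2 change by labelled genotype of each tested gene along chromosome 7 in muscle and testis (position in Mb, GRCm38), with genes at an unadjusted p below 0.01 in colour, the span within 35 Mb of Bckdk in grey and Bckdk as a dashed line. Within the span 3.97% of muscle genes and 4.22% of testis genes are coloured.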

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

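The tests of chromosome 7, pseudogenes, transcripts of other tissues, opposite lists and slow-fibre genes were chosen after the results were seen, and the counts over other splits were not.

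The effect by genotype label differed between muscle and testis in an interaction test for 2 genes and 8 gene lists, as log2 differences of muscle minus testis. Bckdk differed by -8.14 and NeoR by 3.52. Among the lists, the median differences were -0.24 for cytosolic tRNA synthetases, -0.34 for glycolysis, -0.22 for immediate early genes and 0.26 for the interferon response. They were 0.17 for macrophage markers, 0.36 for endothelial markers, 0.40 for red blood cell markers and 0.16 for collagen and matrix. None of the 8 passed with an estimated correlation (lowest adjusted p = 0.0546). Of 100 regroupings within both tissues, the real one included, 13 gave at least as many genes as the real 2 (highest other 9). Some of these kept the real muscle split, and with it the muscle change of Bckdk, among them those with 9 and 6 genes. Others with 3 or 2 genes did not keep it, so a count of 2 also arose without the real muscle split. As the regroupings mix both kinds, their share cannot decide whether chance gives the real count. The 10 splits of 6 libraries are too few for a share under 0.05. In muscle, 1 of the 10 splits, the real one, reached the real count of 6 genes (highest other 0) and 1 the real count of 15 lists (highest other 12). In testis, 2 of the 10 splits reached the real count of 4 genes and 1 the real count of 11 lists (highest other 6). The other testis split gave 288 genes and sets wild-type A, wild-type B and E labelled mutant against the rest. Their islet sums of 19745, 19565 and 13925 were the highest in testis, but F stood close to E at 13077. The split of A, B and F against the rest gave 0 genes. What sets the 288 genes apart was not tested.

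The first pattern is the excess of genes with an unadjusted p below 0.01 around Bckdk on chromosome 7, over a span of 35 Mb set after the values were seen. An effect of the inserted cassette on the nearest genes alone would leave no excess on chromosome 7 beyond 5 Mb. There, 30 of 1137 muscle genes (2.64%) and 35 of 1419 testis genes (2.47%) had such a p. The shares on other chromosomes were 1.54% and 1.17% (larger Fisher's exact p = 0.00707). Of these genes, 18 and 20 lay at 5 to 35 Mb and so were among those that set the span. Between the preset windows of 5 and 20 Mb, testis had 12 of 283 (Fisher's exact p = 1.90e-04), which argues against that explanation in testis. Muscle had 6 of 240 there (Fisher's exact p = 0.281) and 12 of 137 at 20 to 35 Mb, so the explanation stays open in muscle. Neighbouring genes were counted as independent in these tests. DNA of another strain kept around the mutant allele stays open, since within 20 Mb, the widest window set before the data were examined, testis passed (17 of 450, Fisher's exact p = 4.58e-05) and muscle did not (9 of 392, Fisher's exact p = 0.213, with 3 of 152 within 5 Mb). Whether reads of genes in the span are counted on near-identical pseudogenes elsewhere, as in Rps13-ps1 (99.6% identical to Rps13) and Mrpl48-ps (98.1% identical to Mrpl48), stays open too, since without the called pseudogenes, which prompted the test, 1 of 12 with a best match in the span had a small p against 4 of 487 others (Fisher's exact p = 0.115). An effect of the loss of Bckdk on these genes was not tested and stays open.

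The second pattern is the transcripts of other tissues, and the lists that move in opposite directions in muscle and testis. Pancreas dissected with the tissue is argued against by the genes of pancreatic enzyme-secreting cells, which summed to at most 2.88% of the islet genes in any library. Reads or RNA carried over between libraries remain a candidate explanation, which NeoR, a gene that wild-type mice should lack, does not settle. NeoR stood at 1.29% of the mutant muscle mean in wild-type muscle and at 1.05% of it in wild-type testis. The latter was 14.7% of the mean of testis labelled mutant. These values rest on 2 to 4 reads per wild-type library. Wild-type testis B held 3 reads although its muscle transcripts were nearly absent (Myh4 at 5.00), so NeoR did not follow those. None of the libraries is of islets, so NeoR does not bear on the islet transcripts. Whether the 4 libraries with more islet transcripts form a batch that sets the opposite lists cannot be told apart from the genotype, because these libraries are mutant in muscle and wild type in testis; with the islet difference as a term, which leaves mutant muscle D and wild-type testis C as lone libraries, 1 of the 4 opposite lists, collagen and matrix, kept opposite medians. A difference by genotype in these lists stays open.

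The third pattern is the higher slow-fibre genes in mutant muscle. A differing share of slow muscle in the tissue pieces is a candidate explanation, since the list median spanned 1.48 on the log2 scale among the wild-type libraries alone, more than the difference of the group means of 1.17. The high-islet libraries may also contribute as a batch, since the mutant library with fewer islet transcripts, D, had a list median of 0.68, within the wild-type range of -0.72 to 0.76, while F and G lay above it at 1.21 and 1.47. A fibre type shift in mutant muscle, the biological alternative, was not tested apart from these and stays open.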

How the results depend on the processing

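The alternatives on islet transcripts and on genes carried over from the other tissue were chosen after the results were seen, and the others were not. Of the named genes' values under alternatives other than leaving out a library, 2228 kept their direction and side of the threshold, 34 were lost, 25 were gained and 8 moved. Of the lists' values, 645 were kept, 48 were lost, 8 gained, 33 moved and 8 reversed. Bckdk in muscle ranged from -7.40 to -5.57 and passed in all 14 settings, and Gdpd3 from 3.68 to 5.01, also in all 14. DESeq2 gave 36 genes in muscle, 10 in testis, 50 for the difference between tissues, 2 shared between tissues and 2 neighbours of Bckdk in testis. All 12 libraries in one model gave 28 genes in muscle, 2 shared genes and 6 lists in testis. No filter gave 14 genes in muscle and 1 for the difference, and a mean of at least 50 gave 1 in testis and 1 for the difference. In testis a pseudocount of 0.5 gave 1 gene, TMM scaling 1, rlog values 2 and eBayes without a trend 0, and edgeR gave 1 for the difference. Without a trend there were 0 shared genes and 1 neighbour of Bckdk in muscle. With an estimated correlation 0 lists passed in either tissue. The islet difference as a term and leaving out the libraries with more islet transcripts both estimate the effect from the same lone libraries, mutant D in muscle and wild-type C in testis, assumed to vary like the others, so they are not separate evidence. Either gave 1 gene in testis, 1 for the difference, 8 lists in muscle and 4 in testis. Other scalings changed the median of all genes by less than 0.1 on the log2 scale, a limit that the medians of several testis lists did not exceed either. Apart from the no-filter and mean-filter settings, which change the genes tested, the cause was not tested.

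With the islet difference as a term, muscle medians reversed to 0.10 for glycolysis, -0.11 for the interferon response, -0.15 for macrophage markers and 0.00 for excitation and calcium release, and with those libraries left out to 0.10, -0.11, -0.16 and 0.00. The interferon response also reversed without mutant muscle G (-0.059, and up to 0.33 over the libraries left out), and adipocyte markers without wild-type muscle C (-0.16, and up to 1.37). The cause was not tested. Leaving out 1 library at a time gave 3 to 497 genes in muscle (497 without mutant D, 89 higher and 408 lower), 1 to 6 in testis and 1 to 951 for the difference. Among the 497, with the high-islet F and G as the only mutants, were 145 genes at under 3% of their testis level, all lower, and 10 of the 12 islet genes, all higher. It gave 9 to 17 lists in muscle, 7 to 13 in testis, 1 shared gene throughout, 1 to 6 neighbours of Bckdk in muscle and 0 to 2 in testis. NeoR, Mrpl48-ps and Gm10167 fell below the filter, and so had no value, in some of the smaller sets.

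No paired analysis was possible within a tissue because wild-type and mutant mice are different animals and the replicate numbers of the titles are not tied to the columns. For the difference between tissues, the mouse number was used as a block, which gave 2 genes, the same 2. Deviations of the muscle and testis libraries of 1 mouse correlated at -0.036 to 0.009 across genes in 5 mice, 0 of them over 0.1, with a consensus correlation of -0.051. At the depth of these libraries 16246 genes in muscle and 19543 in testis passed the filter on low values. Depth was not varied, and the simulated recovery of genes changed 1.5-fold was 10% in muscle and 64% in testis.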

Other observations

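The genes in this part were chosen after their values were seen, and no test of an explanation was made for them.

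Mutant muscle also held less of the immunoglobulin heavy chain transcript Ighm, a marker of B cells, at 2576, 2353 and 2167 normalised counts in wild-type A, B and C and 1415, 1045 and 981 in mutant D, F and G (log2 change -1.06, SE 0.16, adjusted p = 0.0779 by limma), which did not pass. It was called with DESeq2, with no filter on low values and without mutant D, where the high-islet F and G were the only mutants. Genes of brown and white fat varied between libraries of both genotypes. Ucp1, the uncoupling protein of brown fat, was 1007, 307 and 3.85 in wild-type A, B and C and 409, 137 and 2882 in mutant D, F and G. Adipoq, the adiponectin gene, was 3061, 2127 and 469 and 1730, 2112 and 5986 in the same order. Amd2, a copy of the polyamine enzyme gene Amd1 whose reads can be shared with related sequences, was 124, 754 and 1881 in wild-type A, B and C and 127, 75.4 and 119 in mutant D, F and G, and was called without wild-type A.

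On chromosome 17, the neighbours Dynlt1b and Tmem181b-ps had higher means in both tissues without passing. Dynlt1b was called in testis without E labelled mutant, and Tmem181b-ps in muscle without mutant D, where the high-islet F and G were the only mutants. Dynlt1b had log2 changes of 0.82 (adjusted p = 0.519) in muscle and 0.68 (adjusted p = 0.469) in testis by limma, and Tmem181b-ps of 0.77 and 0.53. Both belong to families with near-identical copies, so their values are uncertain.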
